A study of Mus musculus with 18 samples.

How the data were processed

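Expression was measured on 18 Affymetrix mouse gene arrays, hybridised with RNA from phagocytes sorted from the small intestine of VDTR mice, which carry a diphtheria toxin receptor fused to green fluorescent protein (GFP) in intestinal epithelial cells. Per the labels, the mice received diphtheria toxin intraperitoneally at 2 ng per kg and were killed 4 hours later. RNA was taken up in TRIzol, cleaned on columns with DNase, and 1 ng per sample was amplified with the NuGEN WT Ovation Pico system. Live CD45+ CD11c+ MHCII+ cells were gated into 3 populations and each was divided into GFP-plus and GFP-minus cells, which gives 6 groups of 3 arrays. The labels also carry an "n value" of 4, whose meaning is not given in the sources used here, and they do not say whether the 3 replicates of a group came from separate mice.

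The deposited table holds 33793 probes as log2 values, each centred on that probe's own median over the 18 arrays. All 33793 probe medians lay within 1e-05 of 0. The log base was inferred from the values and is not stated in the labels: a single probe spanned up to 10.15 units, more than the 4.82 that log10 of a scanner's range allows. A natural log is less usual for such arrays but was not strictly excluded, so fold changes rest on base 2. The software, the summarisation and the normalization that the authors used are not given in the sources used here. Centring removed the absolute signal, so neither detection above background nor a gene's level relative to another gene can be read from the values. The number of arrays, 3 per group, limits the precision.

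Column medians ran from -0.0377 to 0.0494 and interquartile ranges from 0.2557 to 0.5784. The plan fixed before the data were examined said that values with unequal quartiles would be quantile normalized. This step was set aside after the spread of the columns was seen and before any gene was tested, because forcing equal quartiles on probe-centred values also forces equal amounts of change on every array. It was kept as an alternative setting, and its counts are given where they depart. A brightness filter, the choice of the brightest probe per gene, a stricter filter and an intensity trend in the variance were also planned. They need absolute signal and were not run.

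Probes were assigned to genes with the supplied probe annotation. Of the probes, 23521 had 1 gene symbol, 1814 had several and 8458 had none. Probes with 1 symbol were averaged per gene, which affected 1082 genes and left 22180 genes for testing. Probes with several symbols or none, 10272 in all, were tested separately. No coordinates are given, because the annotation of the array named no genome build.

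A linear model with 1 mean per group was fitted to all 18 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes variances (12 residual and 2.089 prior degrees of freedom). The contrasts were GFP-plus over GFP-minus in each population, the mean of these 3 contrasts, an F-test of whether the GFP effect differed between populations, and the 3 pairs of populations averaged over both GFP gates. P-values are two-sided and Benjamini-Hochberg adjusted over the 22180 genes, with a threshold of 0.05. Standard errors (SE) come from the same fit, with 3 arrays per group. The p-values measure only the spread between these samples. Whether GFP effects ran in parallel across genes was tested by Pearson's r and Spearman's rho over genes, with an exact permutation test on r over the 400 joint relabellings of the arrays of both populations.

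Fixed before the data were examined were 30 gene lists for cell types, pathways and responses, of which 29 held at least 5 measured genes. The erythroid list held fewer and was not tested. Lists were tested with camera at a preset correlation between genes of 0.01, then with the correlation estimated from the data, and with fry. Their p-values were adjusted over the lists within a comparison. Genes named in the text follow a rule fixed at the same time. It takes up to 10 largest rises and 10 largest falls among genes that passed, or the 5 with the smallest p where fewer than 5 passed in a direction. For the F-test it takes the 10 smallest p-values. The 7 sort markers and up to 4 members of each list with the smallest p complete it.

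The procedure was tested on simulated data of the same shape, with 50 genes planted at each size. For the GFP contrast of CD103 dendritic cells (DCs) it recovered 36% of genes planted at a log2 change of 1, 86% at 2 and 98% at 4. For the GFP contrast in the CD103 CD11b CD64 macrophages it recovered 52%, 78% and 98%, and in the CD11b CD64 macrophages 50%, 74% and 98%. False calls numbered 3 of 161 in DCs, 9 of 167 in the macrophages with CD103 and 10 of 165 in those without. Camera called 2 of 2 planted lists. The simulated noise was independent between genes, and each gene had the same variance on all arrays. Real array weights ran from 0.352 to 2.52, and genes of a list can move together. Recovery in the data may therefore be lower, and camera was not tested on correlated genes.

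Settings varied as fixed beforehand were quantile normalization, centring each array on its median, single probes in place of gene means, only the arrays compared, array weights, the mean of the enterocyte list as a covariate, a 2-fold minimum, the replicate number as a fixed or random block, single GFP gates for the population contrasts, and leaving out each array in turn. Chosen after seeing the data were leaving out the 4 arrays of lowest estimated weight, testing only the more variable part of the genes, a lymphocyte covariate, and leaving out each array in turn for the gene lists. The labels do not say whether equal replicate numbers share mice or sorts, and arrays of equal number were only weakly alike, so samples were treated as unpaired.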

Results

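The data describe 3 populations of phagocytes from the small intestine, 4 hours after diphtheria toxin was given to mice whose epithelial cells carry the toxin receptor and GFP. The populations were CD103 DCs (CD103+ CD24+), macrophages with CD103, CD11b and CD64, and macrophages with CD11b and CD64. GFP-plus phagocytes are those taken to hold material from epithelial cells, and GFP-minus cells of the same gate are their controls. Each of the 6 groups had 3 arrays. Values are log2 and relative to each probe's median over the 18 arrays, so differences between groups are measured and absolute levels are not. The first principal component, with 32.7% of the variance, parted DCs from both macrophage populations. The second, with 15.9%, parted GFP-plus from GFP-minus DCs. Its highest scores, 45.4 to 62.2, were those of the 4 arrays of lowest estimated weight, which were macrophage arrays and GFP-plus DC replicate 1. GFP-plus DC replicate 2, at -14.1, lay within the range of the macrophage arrays. This component therefore does not separate GFP in DCs from array quality. Arrays of 1 group correlated at r = 0.525 to 0.57 in GFP-plus DCs and at r = 0.564 to 0.715 in GFP-minus DCs. The range was 0.054 to 0.39 in GFP-plus and 0.00925 to 0.262 in GFP-minus CD103 CD11b CD64 macrophages, and 0.378 to 0.564 in GFP-plus and -0.0897 to 0.295 in GFP-minus CD11b CD64 macrophages. These correlations were taken on values centred on the median of 18 arrays, most of them macrophage arrays. They are higher for a group far from that median, so they do not rank the quality of the replicates between populations.

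The first question was how CD103 DCs that hold epithelial material differ from those that do not. GFP-plus DCs had more RNA for genes of mature, migrating DCs: the 21 measured genes of that list had a median log2 change of 1.24 (camera adjusted p = 1.14e-10, held at adjusted p = 0.00546 with an estimated correlation). Fscn1, which bundles actin in mature DCs, was higher by 3.56 ± 0.32 log2 (SE, 11.8-fold), and the chemokine gene Ccl17 was higher by 2.85 ± 0.47. Il12b, which encodes a subunit of interleukin 12, was higher by 2.99 ± 0.35. Kif11 and Cenpe, 2 of the 26 cell cycle genes, were lower by -1.79 ± 0.36 and -1.69 ± 0.35. Defa24, an antimicrobial peptide gene of Paneth cells, was higher by 4.34 ± 0.54.

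In limma, 351 of 22180 genes passed a Benjamini-Hochberg adjusted p of 0.05, of which 72 were higher and 279 lower in GFP-plus DCs. Among them 310 changed at least 2-fold. All GFP-plus arrays lay on 1 side of all GFP-minus arrays in 20.1% of the 22180 genes, where chance gives 10%, and in all of the 351 except Cdkn1a, which is expected of genes selected on the same arrays. Other large rises were Glipr2 (4.42 ± 0.63), Gclc (3.81 ± 0.37), which encodes the catalytic subunit of the first enzyme of glutathione synthesis, Fabp6 (3.93 ± 0.89), a bile acid binding protein gene of ileal enterocytes, Nudt17 (3.26 ± 0.30) and Adcy6 (2.77 ± 0.36). The largest falls were Dapk2 (-4.32 ± 0.35), a death-associated kinase gene, and Gzma (-3.88 ± 0.47), the gene for granzyme A. Il1r2, a decoy receptor for interleukin 1, changed by -3.78 ± 0.81. Other falls were the immunoglobulin gene Igkv6-14 (-3.43 ± 0.40), P2ry14 (-3.39 ± 0.76), Alg5 (-3.16 ± 0.44), Ndrg3 (-3.14 ± 0.56), Trit1 (-3.14 ± 0.27) and Haspin (-3.04 ± 0.27). Adjusted p-values in limma with Benjamini-Hochberg ran from 3.76e-05 for Dapk2 to 0.0439 for Fabp6 among these genes.

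Of the 21 measured genes of the DC maturation and migration list, 19 were above 0 and 4 rose (Fscn1, Ccl17, Cd274 and Relb), or 10 when adjusted over the list alone. Cd274, which encodes PD-L1, rose by 1.64 ± 0.31 and Relb, an NF-kB subunit gene, by 1.31 ± 0.30 (limma, Benjamini-Hochberg adjusted p = 0.0212 and 0.0444). The inflammatory list of 32 genes was not called, with a median of 0.096 and a camera adjusted p of 0.121, and its members went both ways: Tnf rose by 1.71 ± 0.35 and Cxcl16 by 0.76 ± 0.15, while Il1a fell by 2.22 on the log2 scale. Tnfaip3 and Nr4a3, from the list of negative regulators of inflammation, rose by 1.79 ± 0.38 and 1.63 ± 0.38, while that list of 26 genes was not called (camera adjusted p = 0.437). Cd63, a tetraspanin gene of late endosomes, rose by 2.52 ± 0.18 (limma, Benjamini-Hochberg adjusted p = 1.02e-05) and Lamp1 by 1.18 ± 0.22, whereas the lysosomal lipase gene Lipa fell by 1.63.

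Several lists moved down in GFP-plus DCs at the preset correlation. Of 26 cell cycle genes 3 fell (Kif11, Cenpe and Bub1), or 8 adjusted over the list alone, with a median of -0.85 (camera adjusted p = 7.99e-07, and adjusted p = 0.129 with an estimated correlation). Of 20 macrophage genes 2 fell, Lyz2 (-0.92 ± 0.20) and the complement gene C1qa (-1.53 ± 0.35), or 4 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 0.000653, and adjusted p = 0.165 with an estimated correlation). None of 19 cholesterol synthesis genes passed in limma over all genes, 8 had an unadjusted p under 0.05, and 6 fell when adjusted over the list alone; the median was -1.08 (camera adjusted p = 0.00289, and adjusted p = 0.286 with an estimated correlation). None of 25 nuclear genes of oxidative phosphorylation passed in limma over all genes, 7 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone; the median was -0.69 (camera adjusted p = 0.000653, and adjusted p = 0.42 with an estimated correlation). Of 12 B and plasma cell genes Ighm fell by 2.00, the 1 member that passed over all genes and also adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.0418, and adjusted p = 0.165 with an estimated correlation); this call was lost without GFP-plus replicate 2 or 3 (camera adjusted p = 0.166 and 0.0762) and without GFP-minus replicate 1 (0.126, with a median of -0.201). The T and innate lymphocyte list (15 genes, median -0.206) and the monocyte list (9 genes, median -0.077) were not called in DCs (camera adjusted p = 0.0615 and 0.0584), although 13 and 6 of their genes stood below 0, Gzma among them, and the list means were lower on all GFP-plus than on all GFP-minus DC arrays. Without GFP-plus replicate 1 both were called (camera adjusted p = 0.0422 each), and without GFP-minus replicate 1 the monocyte list was (0.0393). DC lineage markers moved singly: Gcsam (-2.90 ± 0.31) and Notch2 (-1.43 ± 0.29) fell, while Xcr1 (-0.83 ± 0.53) and Itgae (-0.23 ± 0.65) did not pass.

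Of the epithelial lists the enterocyte one was not called in DCs. Of 15 secretory epithelium genes Defa24 rose, the 1 member that passed over all genes and also adjusted over the list alone, with a list median of 0.20 (camera adjusted p = 0.0152, and adjusted p = 0.12 with an estimated correlation). The call was lost without GFP-plus replicate 3 (camera adjusted p = 0.0691), and the median was 0.125 without GFP-plus replicate 2. Other Paneth cell defensins, tallied after Defa24 had been seen, lay on the same side: all 10 defensin genes with probes of their own, Defa24 included, and all 9 probes shared by several of them stood above 0, and Defa24 and 6 of the shared probes passed (limma, Benjamini-Hochberg). The 40 enterocyte genes had a median of 0.05 (camera adjusted p = 0.0725). Among them Fabp1 was at 2.81 ± 0.71 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0655), while Fabp6, an enterocyte gene outside the list, passed.

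GFP-plus DC arrays had a wider spread of values, with interquartile ranges of 0.578, 0.394 and 0.474 against 0.375, 0.278 and 0.293 in GFP-minus DCs, and quantile normalization gave 48 genes, 24 higher and 24 lower, in place of 72 and 279. The count was 63 with the lymphocyte covariate, 28 higher and 35 lower, so the excess of falls varied with both choices. It was 85 when only DC arrays were fitted (15 higher, 70 lower) and 88 with the enterocyte covariate (16 and 72). The means of both covariate lists part all GFP-plus from all GFP-minus DC arrays. Either covariate therefore also removes part of the GFP contrast, and a call lost with it does not name a cause. Without GFP-minus replicate 2 or 3 the count was 118 or 122, without GFP-plus replicate 1 or 3 it was 163 or 222, and without GFP-plus replicate 2 it was 711. Ccl17 did not pass after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.162), when only DC arrays were fitted (0.1) or with the enterocyte covariate (0.0915). Fabp6, Il1r2, P2ry14, Alg5 and Ndrg3 were lost under the same 3 settings, and Fabp6, Il1r2, P2ry14 and Ndrg3 also when some single arrays were left out. Gzma was lost after quantile normalization, and Glipr2, Nudt17 and Adcy6 when only DC arrays were fitted. Kif11 and Cenpe did not pass under these 3 settings or with the lymphocyte covariate.

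**Figure D1:**
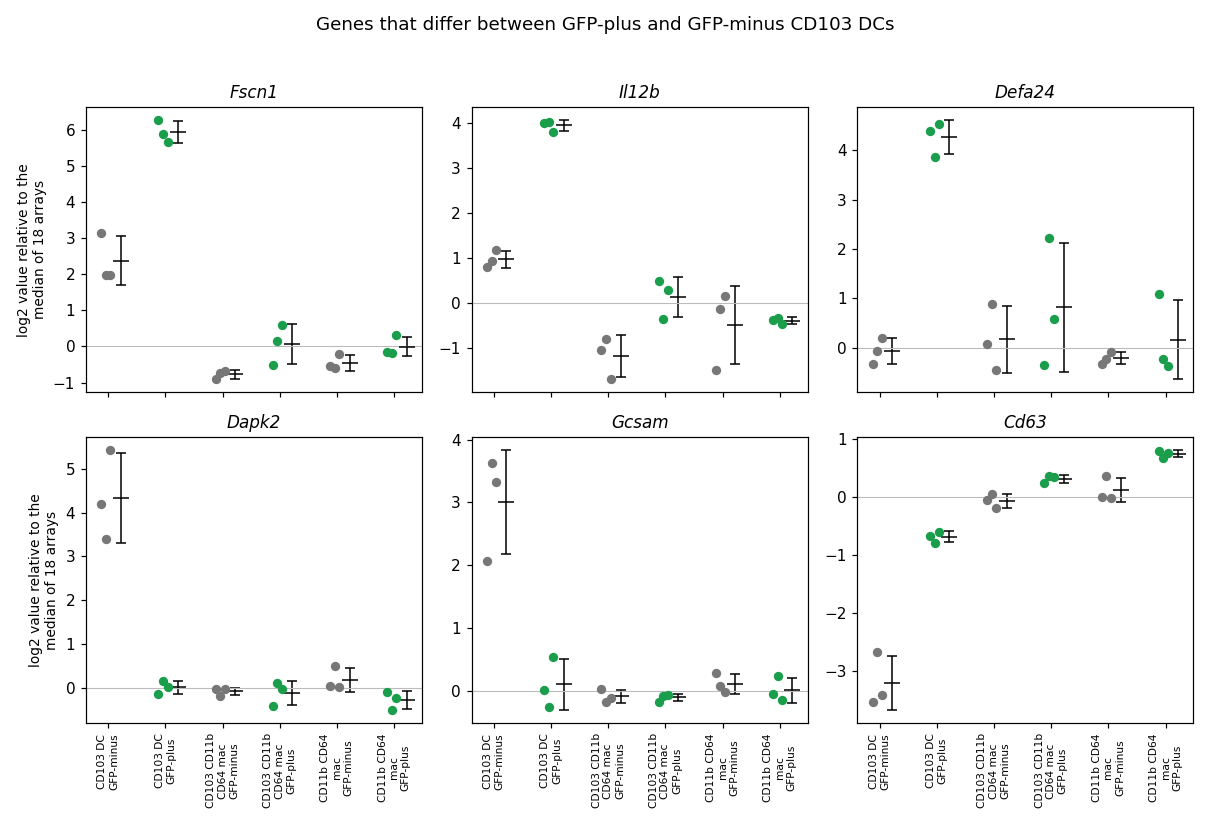
Log2 values relative to the median of 18 arrays (vertical axis) for 6 genes in the 6 groups; points are single arrays, and the bar beside them gives mean and SD (n = 3). Fscn1, Il12b, Defa24 and Cd63 were higher, and Dapk2 and Gcsam lower, in all 3 GFP-plus than in all 3 GFP-minus CD103 DC arrays.

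The same question was asked of macrophages with CD103, CD11b and CD64. GFP-plus cells had more RNA for Ms4a14 (3.40 ± 0.49), the secreted phospholipase gene Pla2g2d (2.78 ± 0.41) and Epb41l3 (2.40 ± 0.32), which encodes a protein of the cortical cytoskeleton. They had less for Cd7 (-3.61 ± 0.56), a surface protein gene of T and natural killer cells, and for the actin regulators Lsp1 (-2.80 ± 0.34), Gsn (-1.64 ± 0.24) and Coro1a (-1.55 ± 0.25). The 15 T and innate lymphocyte genes had a median of -1.07 (camera adjusted p = 3.22e-06, and adjusted p = 0.192 with an estimated correlation), which was -0.287 without GFP-minus replicate 3. Plac8 and Ccr2, genes of inflammatory monocytes, were at -2.71 ± 0.49 and -2.47 ± 0.57 and did not pass.

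In limma, 12 of 22180 genes passed a Benjamini-Hochberg adjusted p of 0.05, 6 in each direction. The other rises were Myo9a (2.35 ± 0.34), Adamdec1 (1.70 ± 0.26) and Lig4 (1.17 ± 0.17), and the other falls the translation genes Eef1g (-1.08 ± 0.17) and Eif3f (-0.98 ± 0.16). Adjusted p-values (limma, Benjamini-Hochberg) lay between 0.0216 for Lsp1 and 0.0439 for Coro1a, and in all 12 genes the GFP-plus arrays lay on 1 side of the GFP-minus arrays, as in 13% of all genes (10% by chance). None of 15 T and innate lymphocyte genes passed in limma over all genes, 6 had an unadjusted p under 0.05, and 6 fell when adjusted over the list alone, with Nkg7 at -2.87 ± 0.57 and Cd3d at -2.23 ± 0.58. None of 9 monocyte genes passed over all genes in limma, 4 had an unadjusted p under 0.05, and adjusted over the list alone 3 fell and 1 rose. Their median was -0.40 (camera adjusted p = 0.00293, and adjusted p = 0.183 with an estimated correlation), a call lost without GFP-minus replicate 3 (camera adjusted p = 0.0541). None of 25 oxidative phosphorylation genes passed over all genes in limma, 8 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone; the median was -0.58 (camera adjusted p = 7.23e-09, and adjusted p = 0.233 with an estimated correlation). Much of this fall came from GFP-plus replicate 1, an array of low weight (0.352): the list mean was -1.46 on that array against -0.103 and -0.324 on the other GFP-plus arrays, and the median was -0.36 without it. The antigen presentation list (median -0.25), the B and plasma cell list (median -0.29) and the macrophage list (median 0.23) were called at camera adjusted p-values of 0.00293, 0.0493 and 0.0411, all lost with an estimated correlation at adjusted p = 0.233, 0.233 and 0.578. Single arrays also ended these calls: the first without GFP-minus replicate 1 or GFP-plus replicate 1 (camera adjusted p = 0.0566 and 0.0501, with a median of -0.057 in the latter case), the second without GFP-minus replicate 1 or 3 or GFP-plus replicate 1 or 2 (0.147, 0.298, 0.0636 and 0.173), and the third without GFP-minus replicate 2 or GFP-plus replicate 3 (0.375 and 0.146), with a median of 0.145 without GFP-plus replicate 2. Adjusted over the list alone, 4 of 20 macrophage genes rose. The integrin gene Itgae, which encodes the sort marker CD103, was at -2.07 ± 0.65 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.282).

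No gene passed when only these 6 arrays were fitted in limma (1707 genes had an unadjusted p under 0.05) or with the enterocyte covariate (1929 genes), while quantile normalization gave 62 genes (20 higher, 42 lower), array weights 95 (52 and 43), the lymphocyte covariate 59 (57 and 2) and the removal of the 4 low-weight arrays 30 (19 and 11). Without GFP-minus replicate 3 the count was 60 (47 and 13), without GFP-plus replicate 1 it was 30 (26 and 4) and without GFP-plus replicate 2 it was 23 (10 and 13), so the balance of rises and falls rests on the setting.

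In macrophages with CD11b and CD64 but without CD103, GFP-plus cells again had more RNA for Epb41l3 (2.50 ± 0.32) and less for Lsp1 (-2.69 ± 0.34). Plac8, a gene of monocytes, was lower by -3.62 ± 0.49. The anthrax toxin receptor gene Antxr1 (1.09 ± 0.14) and the adhesion gene Fblim1 (1.80 ± 0.26) were higher, and the pseudogene S100a11-ps (-2.41 ± 0.33) was lower. Of 31 lysosome genes 30 stood above 0, with a median of 0.34 (camera adjusted p = 3.8e-07, and adjusted p = 0.265 with an estimated correlation).

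These 6 genes, 3 in each direction, were all that passed among 22180 in limma with Benjamini-Hochberg adjusted p-values from 0.0155 for Lsp1 to 0.0295 for Fblim1, and in each the GFP-plus arrays lay on 1 side of the GFP-minus arrays, as in 15.9% of all genes (10% by chance). Next by p-value, and not passing, were the ion transporter gene Slc12a2 (2.97 ± 0.52) and Gm13391 (1.27 ± 0.22) on the higher side. On the lower side they were Mir452 (-0.84 ± 0.15) and Alox5ap (-2.88 ± 0.55), a gene of leukotriene synthesis. Of 9 monocyte genes Plac8 fell, or 3 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.000129); this call held at adjusted p = 0.0454 with an estimated correlation, but not without GFP-minus replicate 3 (0.288) or GFP-plus replicate 2 or 3 (0.102 and 0.0824). None of 31 lysosome genes passed in limma over all genes or over the list alone, and 6 had an unadjusted p under 0.05. None of 28 genes for recognition and uptake of apoptotic cells passed in limma over all genes, 8 had an unadjusted p under 0.05, and 7 rose adjusted over the list alone. Their median was 0.29 (camera adjusted p = 0.000106, and adjusted p = 0.265 with an estimated correlation), with the receptor gene Mertk at 2.20 ± 0.41 and its ligand gene Gas6 at 2.11 ± 0.48. The macrophage list (median 0.28), the lipid handling list (median 0.45) and the cholesterol synthesis list (median 0.56) were called at camera adjusted p-values of 0.000407, 0.000466 and 0.00255. With an estimated correlation they were lost, at adjusted p = 0.265, 0.317 and 0.413. The lipid median was 0.701 without GFP-minus replicate 3 and 0.287 without GFP-plus replicate 3, and the cholesterol median was 0.295 without GFP-minus replicate 1. The enterocyte list had medians of 0.09 in macrophages with CD103 and 0.03 in those without, and was called in neither (camera adjusted p = 0.618 and 0.403).

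No gene passed with the enterocyte covariate in limma (634 genes had an unadjusted p under 0.05), nor without GFP-minus replicate 1 (813 genes), GFP-plus replicate 2 (1169 genes) or GFP-plus replicate 3 (866 genes). The count was 1 without GFP-minus replicate 2, 34 without GFP-minus replicate 3, 22 after quantile normalization and 53 with array weights.

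**Figure D2:**
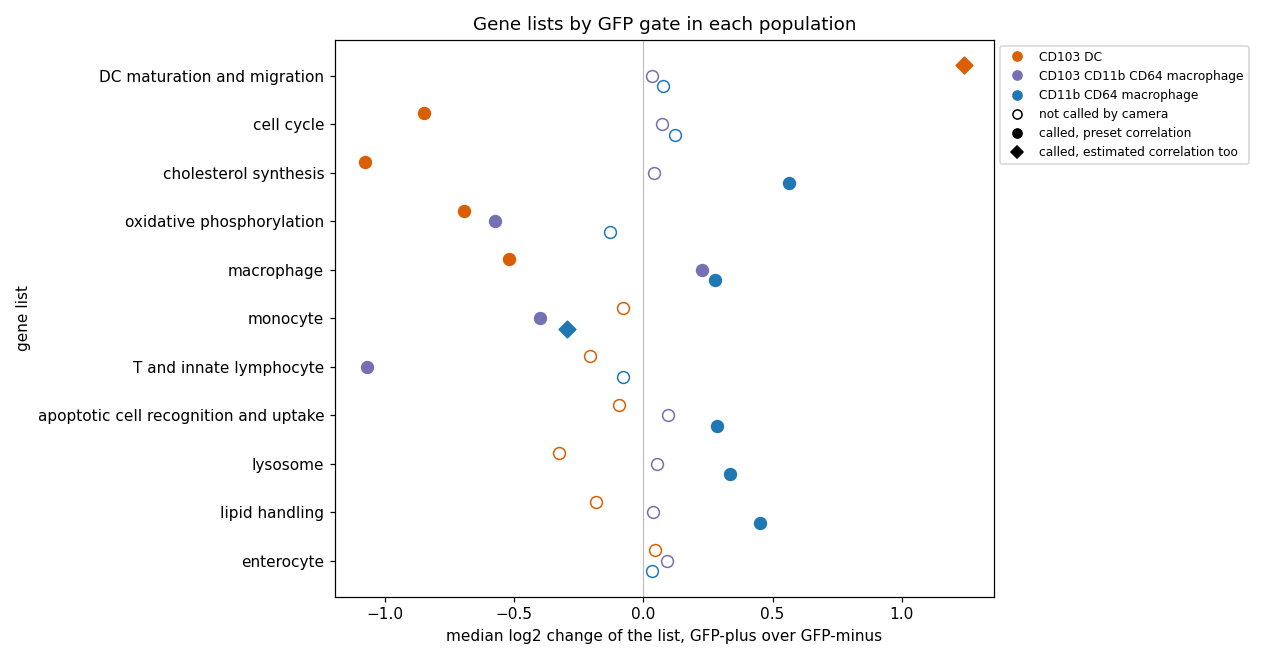
Median log2 change of 11 gene lists, GFP-plus over GFP-minus (horizontal axis), in CD103 DCs, CD103 CD11b CD64 macrophages and CD11b CD64 macrophages. Open symbols were not called by camera, filled circles were called at the preset correlation alone, and diamonds were also called with an estimated correlation: the maturation list in DCs (1.24) and the monocyte list in CD11b CD64 macrophages (-0.29).

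What GFP-plus cells shared was asked by the mean of the 3 GFP contrasts. Among the largest rises were a pair of enterocyte genes: Fabp1, for a fatty acid binding protein, was higher by 2.23 ± 0.41, and Rbp2, for a retinol binding protein, by 1.64 ± 0.33. Among the largest falls were monocyte genes: Plac8 was lower by -2.75 ± 0.28, the chemokine receptor gene Ccr2 by -2.13 ± 0.33 and Ly6c2 by -1.98 ± 0.34. All GFP-plus arrays lay on 1 side of all GFP-minus arrays in 3 of 3 populations for Plac8, Ccr2 and Fscn1, and in 2 for Fabp1, Rbp2 and Ly6c2.

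In limma, 91 of 22180 genes passed a Benjamini-Hochberg adjusted p of 0.05, 41 higher and 50 lower, and 54 of them by at least 2-fold. Further rises were Defa24 (1.79 ± 0.31), Fscn1 (1.62 ± 0.18), Slc12a2 (1.61 ± 0.30), Epb41l3 (1.59 ± 0.19), Ms4a14 (1.48 ± 0.28), Il12b (1.47 ± 0.20), Gclc (1.46 ± 0.22) and the glycolysis regulator Pfkfb3 (1.44 ± 0.18). Further falls were Ifitm6 (-2.29 ± 0.43), S100a10 (-1.82 ± 0.33), S100a4 (-1.78 ± 0.35), Gzma (-1.82 ± 0.27), Lsp1 (-1.78 ± 0.20), the integrin gene Itgb7 (-1.77 ± 0.19) and Napsa (-1.75 ± 0.26). Adjusted p-values (limma, Benjamini-Hochberg) ran from 0.00136 for Plac8, Lsp1 and Itgb7 to 0.0491 for Rbp2. A mean can rest on 1 or 2 populations, and 6 of these 20 genes also passed the F-test for a GFP effect that differs between populations (limma, Benjamini-Hochberg): Gclc (adjusted p = 0.00746), Fscn1 (0.0104), Lsp1 (0.0183), Epb41l3 (0.0225), Gzma (0.0251) and Il12b (0.0466). Gzma was at -3.87 in DCs, -2.02 in macrophages with CD103 and 0.43 in those without, and in the same order Fscn1 was at 3.56, 0.85 and 0.45, Il12b at 2.99, 1.32 and 0.09, Gclc at 3.81, -0.16 and 0.72, Epb41l3 at -0.14, 2.40 and 2.50, and Lsp1 at 0.15, -2.80 and -2.69. Defa24 was at 4.34, 0.65 and 0.38 (adjusted p = 0.0502). Fabp1 was at 2.81, 1.84 and 2.03 in the same order, and Rbp2 at 0.53, 2.33 and 2.07. Fabp2, another enterocyte gene, was at 2.43 ± 0.52 in the mean and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0633).

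Of 9 monocyte genes 3 fell over all genes and also adjusted over the list alone, with a median of -0.48 (camera adjusted p = 2.4e-05), a call held at adjusted p = 0.0252 with an estimated correlation, but not without GFP-minus replicate 2 or 3 or GFP-plus replicate 3 of the macrophages with CD103 (0.0586, 0.0594 and 0.0604). Of 21 maturation genes Fscn1 and Cd274 rose, or 5 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 1.57e-05), held at adjusted p = 0.0422 with an estimated correlation. This mean rests on DCs: the median was 1.24 there but 0.032 and 0.076 in macrophages with and without CD103, where the list was not called (camera adjusted p = 0.618 and 0.966). The call with an estimated correlation was lost, at adjusted p = 0.0529 to 0.0902, without any 1 of 11 arrays: all GFP-plus arrays and GFP-minus replicates 2 and 3 of the macrophages with CD103, all GFP-minus arrays and GFP-plus replicate 1 of those without, and GFP-plus replicate 3 and GFP-minus replicate 1 of the DCs. The median was 0.194 without GFP-plus replicate 2 of the DCs. Of 15 T and innate lymphocyte genes Gzma fell, or adjusted over the list alone 4 fell and 1 rose, with a median of -0.71 (camera adjusted p = 5.07e-05, and adjusted p = 0.131 with an estimated correlation). None of 25 oxidative phosphorylation genes passed over all genes in limma, 11 had an unadjusted p under 0.05, and 8 fell adjusted over the list alone, with a median of -0.39 (camera adjusted p = 4.76e-10, and adjusted p = 0.131 with an estimated correlation). The cell cycle (median -0.21), B and plasma cell (-0.21), cDC2 (-0.24) and uptake (0.07) lists were called at camera adjusted p-values of 0.0032, 0.00469, 0.0172 and 0.0338. All were lost with an estimated correlation, at adjusted p = 0.286, 0.0951, 0.286 and 0.412. The B and plasma cell median was -0.107 without GFP-minus replicate 1 of the macrophages without CD103 and -0.109 without GFP-minus replicate 1 of the DCs. The cDC2 call was lost without GFP-minus replicate 1 or 3 of the macrophages with CD103 (camera adjusted p = 0.0607 and 0.078), and the median was -0.148 without GFP-minus replicate 3 of those without. The uptake call was lost, at camera adjusted p = 0.0563 to 0.121, without any 1 of 8 arrays: GFP-minus replicate 2 and GFP-plus replicate 3 of the macrophages with CD103, GFP-minus replicates 1 and 2 and GFP-plus replicate 3 of those without, and GFP-plus replicates 2 and 3 and GFP-minus replicate 1 of the DCs. Its median was 0.139 without GFP-plus replicate 1 of the DCs and 0.114 and 0.107 without GFP-plus replicates 1 and 2 of the macrophages with CD103. Among cDC2 genes Cd209a fell by 1.01. The enterocyte list as a whole had a median of 0.06 and was not called (camera adjusted p = 0.0523). Single genes outside these lists' calls were Cd63 (1.18 ± 0.11), the interferon-induced gene Oasl1 (1.28 ± 0.21) and the RNA sensor gene Tlr7 (0.63 ± 0.12), which rose.

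With the enterocyte covariate 2 genes passed, Plac8 and Gzma. Fabp1 and Rbp2 belong to that covariate, and its mean was higher on all GFP-plus than on all GFP-minus arrays of each population. Quantile normalization gave 164 genes and array weights 177. With the lymphocyte covariate 80 genes passed, 68 higher and 12 lower, of which 28 were among the 91, so the balance of rises and falls also rests on the setting. Gzma belongs to the lymphocyte covariate and did not pass with it. Rbp2 passed neither after quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0578) nor with array weights (0.0755), without the 4 low-weight arrays (0.0742) or with the lymphocyte covariate (0.11). Ly6c2 did not pass without the 4 low-weight arrays (0.114), with the lymphocyte covariate (0.146), or without GFP-plus replicate 2 or 3 of the macrophages without CD103 (0.0533 and 0.0615) or GFP-minus replicate 3 of the DCs (0.0545), and Ccr2 did not pass with the lymphocyte covariate (0.101). Of the 20 largest changes 8 passed with that covariate, 14 without the 4 low-weight arrays and 16 after quantile normalization, where Defa24, Gzma and S100a4 were lost with Rbp2. Leaving out 1 array gave 60, 35 and 172 genes without GFP-minus replicates 1, 2 and 3 of the CD11b CD64 macrophages, 40, 43 and 25 without their GFP-plus replicates 1, 2 and 3, 54 without GFP-plus replicate 3 of the CD103 CD11b CD64 macrophages, and 43 and 47 without GFP-minus replicates 2 and 3 of the DCs.

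**Figure D3:**
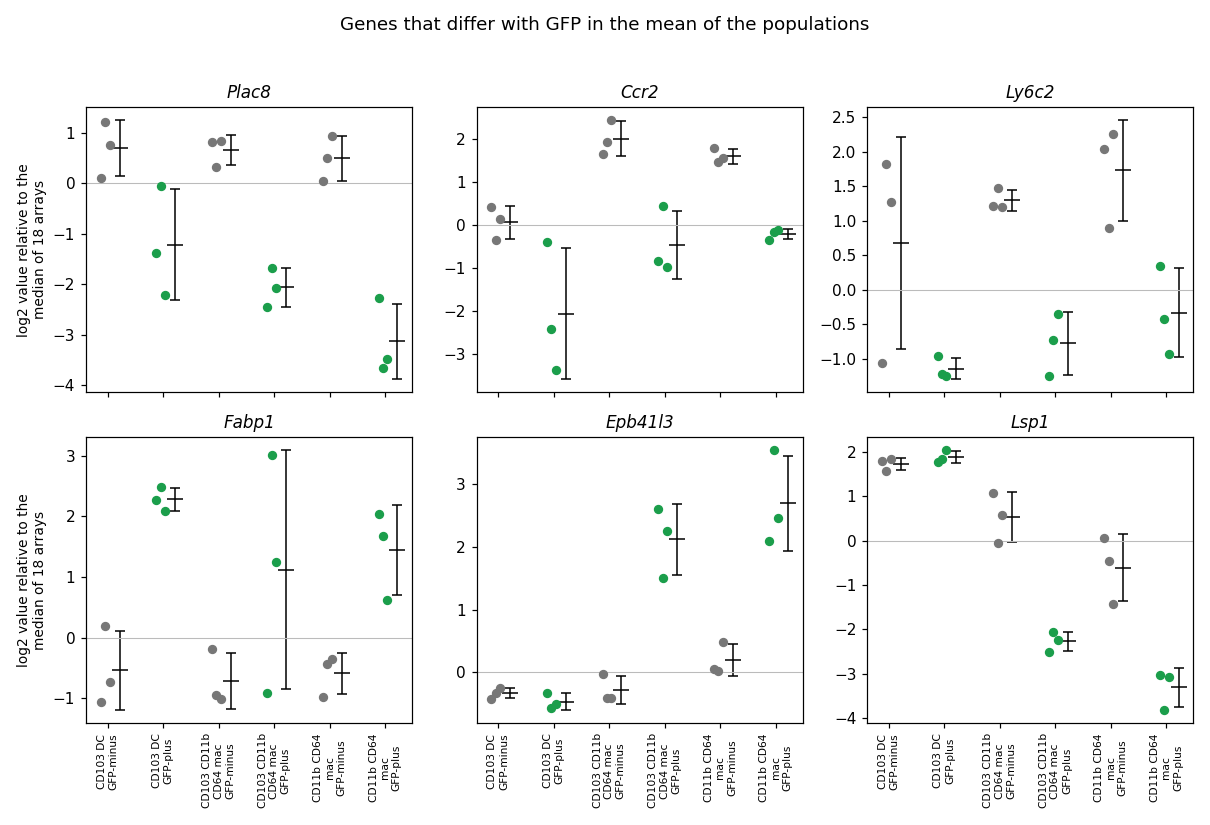
Log2 values relative to the median of 18 arrays (vertical axis) for 6 genes in the 6 groups; points are single arrays, and the bar beside them gives mean and SD (n = 3). Plac8, Ccr2, Ly6c2 and Lsp1 were lower, and Fabp1 and Epb41l3 higher, in the mean of GFP-plus over GFP-minus cells.

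Whether the GFP effect differed between populations was tested directly. Cd63 was higher in GFP-plus DCs by 2.52 against 0.38 and 0.63 in macrophages with and without CD103. Ms4a7, a gene of macrophages, was at -2.38 in DCs against 0.27 and 0.44. Nudt17 was at 3.26 in DCs against -0.14 and 0.06, and Dapk2 at -4.32 against -0.03 and -0.46.

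The F-test passed for 80 of 22180 genes (limma, Benjamini-Hochberg adjusted p of 0.05). After Ms4a7 (adjusted p = 0.000118) came Gm3336, Trit1 and Zfp367. Trit1 was at -3.14 in DCs and at 0.49 and 0.51 in the macrophages, and Zfp367 at -2.74, 0.40 and 0.38. Dapk2, Haspin, Hmgn5, Acadsb, Nudt17 and Cd63 followed at a limma Benjamini-Hochberg adjusted p of 0.00263. Hmgn5 was at -2.89 in DCs and at 1.32 and 0.90 in the macrophages, and the mitochondrial dehydrogenase gene Acadsb at -1.47, 0.68 and 1.22. The maturation list rose more in DCs than in macrophages without CD103, by a median of 0.75 (camera adjusted p = 2e-06), held at adjusted p = 0.0413 with an estimated correlation, but not without any 1 of 7 arrays (0.051 to 0.161): GFP-minus replicates 2 and 3 and GFP-plus replicates 2 and 3 of those macrophages, and GFP-plus replicate 3 and GFP-minus replicates 2 and 3 of the DCs. The median was 1.145 without GFP-plus replicate 1 of the DCs. Against macrophages with CD103 the median was 0.85 (camera adjusted p = 5.18e-06, and adjusted p = 0.0524 with an estimated correlation). The macrophage list differed by -0.92 from each macrophage population (camera adjusted p = 7.82e-06 and 5.9e-06, and adjusted p = 0.128 and 0.12 with an estimated correlation). Across genes, which are not independent replicates, 3 pairs of GFP effects were compared by an exact permutation test over 400 relabellings, whose smallest two-sided p is 0.005. DCs and macrophages with CD103 gave Pearson r = 0.0427 and rho = 0.0219 (exact p = 0.55, adjusted 0.55). DCs and macrophages without CD103 gave r = -0.273 and rho = -0.294 (exact p = 0.03, adjusted 0.09), and both macrophage populations r = 0.363 and rho = 0.271 (exact p = 0.09, adjusted 0.135). Epb41l3 and Lsp1 passed in both macrophage populations, 1 gene each way where 0.00081 would be shared by chance. No gene that passed in DCs passed in either. Chance gives 0.019 shared rises and 0.075 shared falls with CD103 CD11b CD64 macrophages, and 0.0097 and 0.038 with CD11b CD64 macrophages. So few genes passed in macrophages that this absence does not show a difference between the responses.

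Quantile normalization gave 32 genes and array weights 193. Leaving out 1 DC array gave 52 or 226 genes without GFP-plus replicate 1 or 2 and 142, 43 or 41 without GFP-minus replicates 1, 2 or 3, and leaving out a macrophage array gave 209 without GFP-plus replicate 1 of those with CD103, and 52, 50 and 169 without GFP-plus replicates 1 and 3 and GFP-minus replicate 3 of those without.

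The sorted populations were then compared over both GFP gates. DCs had more RNA for Itgae, which encodes CD103, than macrophages with CD103 (4.49 ± 0.46) and without it (5.68 ± 0.46), and more for Cd24a (4.46 and 5.20). They had less for Fcgr1, which encodes CD64 (-4.87 and -4.72), for Itgam, which encodes CD11b (-4.64 and -4.49), and for the macrophage growth factor receptor gene Csf1r (-5.90 ± 0.14 and -6.21 ± 0.14). The endocytic receptor gene Ly75 was higher in DCs by 4.75 ± 0.09 and 4.88 ± 0.09.

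Against macrophages with CD103, 1758 of 22180 genes passed in limma at a Benjamini-Hochberg adjusted p of 0.05, 576 higher and 1182 lower in DCs. Against macrophages without CD103, 1800 passed, 482 higher and 1318 lower. The largest rises in both comparisons included Rab30 (6.28 and 5.98), the inhibitory receptor gene Btla (5.62 and 6.23), Gpr33 (5.40 and 5.54) and Actn1 (5.05 and 5.68). The largest falls in both included the Fc receptor gene Fcgr4 (-5.76 and -5.55) and the complement genes C3ar1 (-5.70 and -5.65) and C1qa (-5.65 and -5.67). Falls named in 1 comparison were the chemokine gene Ccl7 (-5.99), Cx3cr1 (-5.42) and the mannose receptor gene Mrc1 (-5.32) against macrophages with CD103, and Adamdec1 (-6.19) and Mmp9 (-5.91) against those without. The adjusted p in limma with Benjamini-Hochberg was 1.5e-12 and 8.69e-13 for Csf1r, and 1.03e-05 and 8.05e-07 for Itgae.

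All 20 macrophage genes were lower in DCs than in macrophages with CD103 over all genes and adjusted over the list alone (median -4.72), and 19 than in those without (median -4.62). Of 17 cDC1 genes, a DC lineage marked by CD103 and CD24, 14 and 13 were higher over all genes and 16 in each comparison adjusted over the list alone, with medians of 3.17 and 2.99. The macrophage list holds Fcgr1, and the cDC1 list holds Itgae and Cd24a. These are genes of sort markers, so their direction is not independent of the gates. Of 16 core DC genes 9 and 8 were higher, and adjusted over the list alone 11 rose against macrophages with CD103, while 8 rose and 1 fell against those without. Of 31 lysosome genes 21 and 22 were lower and 1 was higher in each, and adjusted over the list alone 24 and 26 were lower and 1 and 2 higher; the medians were -1.32 and -1.52. Of 32 inflammatory genes 19 were lower and 2 higher in each comparison, and adjusted over the list alone 22 and 20 were lower and 4 higher in each, with medians of -1.23 and -1.26. Camera called all these lists, and the calls held with an estimated correlation at adjusted p-values up to 0.00977. The population counts did not move by over 1.5 times when any 1 array was left out; in GFP-minus cells alone they were 805 and 731, and in GFP-plus cells alone 1533 and 2096. With the lymphocyte covariate the count against macrophages with CD103 was 1246, 607 higher and 639 lower, so the excess of falls there rests on that choice; against those without it was 2022, 536 higher and 1486 lower.

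Macrophages with CD103 differed little from those without. They had more RNA for Gzma (3.67 ± 0.33), the scavenger receptor gene Cd163 (3.50 ± 0.39), the complement gene C4b (3.37 ± 0.22) and Spic (2.33 ± 0.34), a transcription factor gene of iron-recycling macrophages. They had less for Adamdec1 (-1.15 ± 0.18) and Gm19434 (-2.03 ± 0.32). Itgae, the gene of the marker that separates the gates, was at 1.19 ± 0.46 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.79), and 4 of the 6 arrays of macrophages with CD103 had values of Itgae from -0.44 to 0.05, close to the -0.53 to -0.05 of those without. The name of this population is that of the gate.

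In limma, 16 of 22180 genes passed a Benjamini-Hochberg adjusted p of 0.05, 14 higher and 2 lower in macrophages with CD103. Other rises were Cd300ld3 (2.10 ± 0.28), Ccl7 (2.00 ± 0.27), Pmp22 (1.91 ± 0.25), Wwp1 (1.59 ± 0.25), Fcrls (1.53 ± 0.25) and the adhesion gene Vcam1 (1.40 ± 0.18), with adjusted p-values (limma, Benjamini-Hochberg) from 5.7e-06 for C4b to 0.0457 for Fcrls. Next on the lower side, and not passing, were Pxdc1 (-2.06 ± 0.36), Hinfp (-0.95 ± 0.18) and Ccl24 (-2.56 ± 0.48). Of 15 T and innate lymphocyte genes Gzma was higher, or 6 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.89e-09, and adjusted p = 0.0635 with an estimated correlation), or 0.353 without GFP-minus replicate 3 of the macrophages with CD103. None of 25 oxidative phosphorylation genes passed in limma over all genes or over the list alone, and 1 had an unadjusted p under 0.05; all 25 were below 0, with a median of -0.38 (camera adjusted p = 1.22e-05, and adjusted p = 0.409 with an estimated correlation), or -0.159 without GFP-plus replicate 1 of the macrophages with CD103, the array of low weight. None of 19 cholesterol synthesis genes passed in limma over all genes, 7 had an unadjusted p under 0.05, and 4 fell adjusted over the list alone, with a median of -0.56 (camera adjusted p = 1.21e-06, and adjusted p = 0.167 with an estimated correlation), or -0.361 and -0.846 without GFP-plus replicates 1 and 3 of the macrophages with CD103.

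The count was 3 when only these macrophage arrays were fitted, 3 in GFP-minus and 9 in GFP-plus cells alone, 33 after quantile normalization (25 higher, 8 lower), 29 with array weights (22 and 7) and 108 with the lymphocyte covariate (30 and 78). Without GFP-plus replicate 3 of the macrophages with CD103 it was 42 (20 and 22), so the excess of rises rests on the setting. Spic lost its call without GFP-plus replicate 3 of the macrophages without CD103 (limma, Benjamini-Hochberg adjusted p = 0.0527). It also lost it when only the macrophage arrays were fitted, in either GFP gate alone and without the 4 low-weight arrays. Cd163 lost its call when only the macrophage arrays were fitted, in GFP-minus cells alone and with the lymphocyte covariate. Gzma lost its call in GFP-plus cells alone. Adamdec1 lost it, at adjusted p = 0.0504 to 0.105, without any 1 of 9 arrays: GFP-minus replicate 2 and GFP-plus replicates 1 and 2 of the macrophages with CD103 and all 6 arrays of those without.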

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

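The tests of a wider spread of values, of epithelial RNA and of macrophage admixture in DCs, of lymphocytes in the macrophage gates, and of what the split with the most genes follows, were chosen after the results were seen.

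The effect of GFP differed between the 3 populations for 80 genes by the limma F-test with Benjamini-Hochberg adjustment. The smallest adjusted p-values were 0.000118 for Ms4a7, 0.000134 for Gm3336, 0.000741 for Trit1 and 0.002 for Zfp367, and Dapk2, Haspin, Hmgn5, Acadsb, Nudt17 and Cd63 shared 0.00263. All 10 of these genes also passed in every alternative run and with each array left out. The count itself moved: it was 52 or 226 without GFP-plus DC replicate 1 or 2, 142, 43 or 41 without GFP-minus DC replicates 1, 2 or 3, 209 without GFP-plus replicate 1 of the CD103 CD11b CD64 macrophages, and 52, 50 and 169 without GFP-plus replicates 1 and 3 and GFP-minus replicate 3 of the CD11b CD64 macrophages. The DC maturation and migration list rose more in DCs than in CD11b CD64 macrophages, with a camera adjusted p = 0.0413 with an estimated correlation, which was lost without any 1 of 7 arrays (0.051 to 0.161). Outside the genes with 1 symbol, 73 of 10272 probes with several symbols or none passed in GFP-plus over GFP-minus DCs (limma, Benjamini-Hochberg), 34 higher and 39 lower.

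The maturation list was higher in GFP-plus than in GFP-minus DCs by a median of 1.24. Epithelial RNA as the source was predicted to raise the enterocyte list by at least as much. The median of that list, 0.046 (SD of its 40 members 0.738), lay below 1.24 by more than its spread. Centring removed the levels, so members near background cannot be separated from unchanged ones, and the low median alone does not exclude this source. The CD45 gate would remove epithelial cells, but not RNA carried by phagocytes. Nor does the list exclude epithelial RNA in these cells. Defa24 (4.34) and Fabp6 (3.93) passed in DCs, as did 6 of 9 probes shared by defensins (median 4.07), and Fabp1 was at 2.81 without passing. Against a loss of macrophage-lineage cells stands the macrophage list, which was lower by less than maturation genes were higher, at -0.52 (SD 0.546; 9 of its 20 genes are on other lists too). Low-quality arrays or the wider spread of values on GFP-plus DC arrays, as the source, would bring the list median under 0.5 once corrected. It was 1.37 (SD of the members 1.07) without the 4 arrays of lowest weight and 1.3 (SD 0.932) after quantile normalization. Neither correction made it smaller than 1.24, although both changed which genes passed. For the wider spread, this argues against it as the source of the list median. It decides little for low-quality arrays. The DC array left out, GFP-plus replicate 1, had the lowest list mean of its group (0.797 against 1.59 and 1.12). The other GFP-plus DC arrays had weights of 0.664 and 0.617, against 0.637, 2.23 and 1.43 in GFP-minus DCs. Array quality was thus not separated from the GFP gate. For single genes both explanations stay open, because the members vary by more than the margin over the bound of 0.5. The prediction written beforehand for low-quality arrays did not ask for a margin beyond that SD, which is not the error of a median. A link between uptake and maturation may also hold, and it stays a hypothesis that the GFP gate alone cannot test.

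Some monocyte and lymphocyte genes were lower in GFP-plus than in GFP-minus macrophages. In the CD11b CD64 gate this was Plac8 and the monocyte list (median -0.29), and lymphocyte genes went both ways, 8 of 15 below 0 and 7 above, from Lat at -0.932 to Cd4 at 2.52, neither passing. In the CD103 CD11b CD64 gate no gene of either list passed in limma (6 of 15 lymphocyte and 4 of 9 monocyte genes had an unadjusted p under 0.05), and both lists were called only at the preset correlation, not with an estimated one (adjusted p = 0.192 and 0.183). None of the technical explanations tested was excluded. Lymphocytes in the GFP-minus CD103 CD11b CD64 gate may contribute, since 11 of 15 lymphocyte genes were lower in GFP-plus cells, among them Nkg7 (-2.87), Cd3d (-2.23) and Gzma (-2.02), although the CD11c and MHCII gates would remove most lymphocytes. For the CD11b CD64 gate the lymphocyte list was at -0.08 (SD 0.796), so the list as a whole did not point to lymphocytes there. Without the 4 arrays of lowest weight the monocyte list was at -0.334 (SD 1.14, camera adjusted p = 8.15e-05), weaker than the -0.484 with all arrays. Both medians lay on the side of their written bounds that speaks against lymphocytes and low-quality arrays. The margins were smaller than the SD of the members, which describes single genes and not the error of a median, so neither explanation was excluded. GFP-minus gates richer in recently arrived monocytes could give the same values, and this was not tested separately.

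Fabp2 was higher in GFP-plus cells by 2.43 ± 0.52 in the mean of the populations without passing (limma, Benjamini-Hochberg adjusted p = 0.0633), and its fellow enterocyte genes Fabp1 and Rbp2 passed, though both lost their call when some single arrays were left out. Against low-quality arrays as the source of the Fabp2 value stands the value without the 4 arrays of lowest weight, 2.26 ± 0.57. Without those arrays Fabp1 was at 2.47 (limma, Benjamini-Hochberg adjusted p = 0.019) and Rbp2 at 1.94, where it no longer passed (adjusted p = 0.0742). Epithelial RNA carried by GFP-plus cells cannot be told apart from expression by the phagocytes: the 14 abundant enterocyte transcripts had a median of 0.174 (SD 0.861), with Apoa1 at 0.12 ± 0.14, Apoa4 at 0.15 ± 0.10 and Reg3b at 0.87 ± 0.54. That median lay on the side of its bound, written beforehand, that speaks against carried epithelial RNA. The margin was smaller than the SD of the members. The prediction did not ask for such a margin, and that SD is not the error of a median. Because centring removed the levels, transcripts near background cannot be separated from those that did not change, so the explanation was not excluded. Engulfed epithelial RNA may therefore account for Fabp1, Fabp2 and Rbp2 without being shown by the list as a whole.

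Other splits of the arrays were counted for each comparison. For GFP within a population 3 arrays against 3 allow 10 splits, too few for a share under 5%. For DCs, 1 of 10 splits gave as many genes as the real 351, and the highest other split gave 21. For CD103 CD11b CD64 macrophages it was 2 of 10, with 12 real and 13 in another, and for CD11b CD64 macrophages 1 of 10, with 6 real and 1 in another. For the mean of the populations 2 of 100 splits gave as many as 91 genes, a share under 5%. The 100 were the real split and others drawn at random, so the share over all possible splits is not known exactly. The highest other split gave 831, several times the real count. That split kept the GFP gates of DCs and of CD11b CD64 macrophages whole. It set GFP-minus DCs on the side of GFP-plus CD11b CD64 macrophages, so GFP itself, with the DC sign turned, enters its count. Among the 100 splits that split had the largest difference between its sides in estimated array weight, in interquartile range and in the second principal component, where the real split ranked 60, 73 and 78. All 4 arrays of lowest weight lay on 1 side of it. Array quality and the GFP differences that it holds cannot be told apart as the source of the 831 genes. The real split had the largest difference in the monocyte and enterocyte list means. For the difference between populations 2 of 100 splits gave as many as 80, also under 5%, and the highest other gave 165. Chance was excluded for the population comparisons, each with 1 of 100 splits: 1758 against 617 at most for DCs over CD103 CD11b CD64 macrophages, 1800 against 560 for DCs over CD11b CD64 macrophages, and 16 against 9 between the macrophages.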

How the results depend on the processing

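The removal of the 4 arrays of lowest weight, leaving out each array for the gene lists, the test of the more variable part of the genes and the lymphocyte covariate were chosen after seeing the data. Centring each array on its median, single probes and a random replicate effect kept all 8 counts within 1.5 times. A stricter filter, the brightest probe and an intensity trend were not run, and no filter and the mean of probes equal the settings used, because the values hold no signal over background. That also means that no limit of detection can be given. No gene list reversed in its camera direction, but 2 called medians near 0 changed sign without 1 array and lost their call: oxidative phosphorylation in DCs over CD103 CD11b CD64 macrophages (0.127 to -0.019 without GFP-plus replicate 1 of the latter) and the macrophage list between the macrophages (0.016 to -0.029 without CD103 CD11b CD64 GFP-minus replicate 1).

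After quantile normalization the counts were 48 for GFP in DCs, 62 in CD103 CD11b CD64 macrophages, 22 in CD11b CD64 macrophages, 164 for their mean, 32 for the difference between populations and 33 between the macrophages. It makes all arrays equally spread, and in DCs all 48 genes were among the 351. Fitting only the arrays compared, with fewer residual degrees of freedom, gave 85 in DCs, 0 in CD103 CD11b CD64 macrophages (limma; 1707 at an unadjusted p under 0.05) and 3 between the macrophages. Array weights gave 95 and 53 in the macrophages with and without CD103, 177 for the mean, 193 for the difference and 29 between the macrophages. The enterocyte covariate gave 88 in DCs, 0 and 0 in the macrophages (limma; 1929 and 634 at an unadjusted p under 0.05) and 2 for the mean. A 2-fold minimum left 54 for the mean. GFP-minus cells alone gave 805 and 731 for DCs over macrophages with and without CD103 and 3 between the macrophages. GFP-plus cells alone, as many arrays, gave 1533, 2096 and 9, so the number of arrays does not account for the lower counts in GFP-minus cells. Without the 4 low-weight arrays the count was 30 in CD103 CD11b CD64 macrophages, 4 of them shared with the 12. The more variable genes gave 123 for the difference and 25 between the macrophages. The lymphocyte covariate gave 63 in DCs, 59 in CD103 CD11b CD64 macrophages, 130 for the difference and 108 between the macrophages. Both covariates overlap with the GFP contrast. The enterocyte mean was higher on all GFP-plus than on all GFP-minus arrays of each population, and the lymphocyte mean was lower in DCs and in CD103 CD11b CD64 macrophages. Calls lost with a covariate therefore do not show that epithelial or lymphocyte RNA caused them. Unless stated, the cause was not tested.

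Pairing by replicate number was weak at most, and it was not excluded. Arrays with the same number in different groups had a mean residual r of 0.0535 (-0.172 to 0.337), and 13 of 45 pairs exceeded 0.1. As a hint towards shared numbers, different numbers had a mean r of -0.0257, and 11 of 18 arrays, not all, were closest to their own number. As a block the replicate number gave 121 for the difference between populations and stayed within 1.5 times for the other 7 counts.

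Leaving out 1 array, where a group of 3 keeps 2, gave ranges of 118 to 711 in DCs, lowest without GFP-minus replicate 2 and highest without GFP-plus replicate 2. The range was 11 to 60 in CD103 CD11b CD64 macrophages (without GFP-minus replicates 1 and 3) and 0 to 34 in CD11b CD64 macrophages (without GFP-minus replicates 1 and 3; limma, 813 genes at an unadjusted p under 0.05 for the 0). It was 25 to 172 for the mean, without GFP-plus and GFP-minus replicate 3 of the CD11b CD64 macrophages, and 41 to 226 for the difference, without GFP-minus replicate 3 and GFP-plus replicate 2 of the DCs. Between the macrophages it was 11 to 42, the latter without GFP-plus replicate 3 of the CD103 CD11b CD64 macrophages. For DCs it was 1492 to 1842 over macrophages with CD103 and 1409 to 1898 over those without.

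Of the 20 largest changes named in DCs, 10 passed when only DC arrays were fitted, 12 after quantile normalization and 13 with the enterocyte covariate; Ccl17 was lost in all 3. Of the largest changes named, 16 of 20 in DCs, 2 of 12 in CD103 CD11b CD64 macrophages (Epb41l3 and Lsp1), 0 of 6 in CD11b CD64 macrophages, 11 of 20 in the mean and 7 of 12 between the macrophages (not Wwp1, Fcrls, Gm19434, Adamdec1 and Spic) passed in limma in each fit without 1 array, against 20 of 20 in each comparison of DCs with macrophages. In single gates 3 named genes reversed: for DCs over CD103 CD11b CD64 macrophages, Defa24 was at -0.242 in GFP-minus cells and Kif11 at -0.126 in GFP-plus cells, and for DCs over CD11b CD64 macrophages Gzma was at -0.676 in GFP-plus cells. Each differs by GFP gate within DCs, and none passed when reversed (limma, Benjamini-Hochberg adjusted p = 0.93, 0.915 and 0.442).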

Other observations

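The comparisons named here were picked from the tables after their values were seen. DCs and macrophages also differed in lists of genes for handling dead cells and lipids, which overlap with the lineage lists. The uptake list shares Mertk, C1qa, C1qb and C1qc with the macrophage list, and the lipid list shares Apoe. In all, 6 of 28 uptake and 4 of 23 lipid genes are on other lists too. Part of the falls below is therefore the lineage difference counted again. Of 28 genes for recognition and uptake of apoptotic cells, 13 were lower and 2 higher in DCs than in macrophages with CD103, and 14 lower and 1 higher than in those without (limma, Benjamini-Hochberg). Adjusted over the list alone, 14 were lower in each, and the medians were -0.74 and -1.11 (adjusted p = 0.0113 and 0.022 with an estimated correlation); the former was -1.18 without GFP-plus DC replicate 2. Of 23 lipid handling genes, 15 and 13 were lower and 2 higher in each, or 15 lower and 2 higher in each adjusted over the list alone, with medians of -1.44 and -1.32 (adjusted p = 0.0113 and 0.0195 with an estimated correlation). Of 12 cDC2 genes, 7 were lower in DCs in each comparison, over all genes and adjusted over the list alone, with medians of -1.13 and -1.06 (adjusted p = 0.0239 and 0.0302 with an estimated correlation). The latter call was lost without GFP-minus replicate 3 of the macrophages without CD103 or GFP-plus DC replicate 2 (0.0525 and 0.0557). The cDC2 list holds Itgam, the gene of the sort marker CD11b, and shares Sirpa with the macrophage list.

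Probes of alpha-defensins, antimicrobial peptides of Paneth cells, were tallied after Defa24 had been seen among the largest rises in GFP-plus DCs. All 10 genes measured by probes of their own stood above 0 (median 0.838), but Defa24 was the 1 that passed (limma, Benjamini-Hochberg). All 9 probes shared by several defensin genes stood above 0 (median 4.07), and 6 of them passed. They share sequence and are not independent. The other Paneth cell genes Lyz1 (1.12 ± 0.50), Ang4 (-0.32 ± 0.44) and Mmp7 (-0.04 ± 0.17) did not pass (adjusted p = 0.306, 0.787 and 0.938). A probe shared by Defa17, Defa2 and Defa3 was higher by 5.93 ± 0.53 (limma, Benjamini-Hochberg adjusted p = 0.000256). Another probe shared by the same genes was higher by 4.23 ± 0.48, 1 shared by Defa28, Defa25 and Defa27 by 4.13 ± 0.47, and 1 shared by Defa33, Defa32 and Defa20 by 2.04 ± 0.22. Such probes do not say which family member was measured. Ferritin light chain, from a probe shared by Ftl1 and a pseudogene, was higher by 0.60 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.00597).

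The GFP-minus CD103 CD11b CD64 arrays were uneven in the genes of their own gate. Itgae stood at 3.44, -0.43 and 2.66 in replicates 1, 2 and 3, against -0.44, -0.15 and 0.05 in the GFP-plus arrays of that population. The CD11b CD64 macrophages without CD103 stood between -0.53 and -0.05, so 4 of the 6 arrays of the CD103 CD11b CD64 gate had about as little Itgae RNA as the gate without CD103. Cd24a, a marker of the DC gate, stood at 1.65, -1.09 and 1.37 in the same GFP-minus arrays. In GFP-minus DCs Itgae lay between 5.28 and 5.56.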
